A study of Drosophila melanogaster with 6 samples.

How the data were processed

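Total RNA of 6 samples of Drosophila S2 cells was measured on Affymetrix Drosophila 2.0 arrays, 1 array per sample, in 2 groups of 3. Per the labels, S2 control cells were wild type, the other cells were induced to make dBigH1, and all received 1 mM copper sulphate for 24 h. The cells carrying dBigH1::FLAG were maintained with hygromycin B before the experiment and grown in the same medium as S2 cells for it. Per the labels' protocols, RNA was extracted on columns and 25 ng per sample was amplified isothermally (SPIA) with biotin label. All 6 labels carry the same date, so no batch could be told by date. The labels number the replicates but do not state separate cultures, so p-values measure only the spread between these samples, which may be technical.

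The deposited values are log2 signals per probe set made by RMA, which corrects background, normalises between arrays and summarises probes, per the submitters' processing notes. The RMA version, the probe annotation behind it and any filter are not given in the sources used here. RMA forces the arrays to a like distribution, so a change common to all transcripts is removed, and differences of dim probe sets are compressed by background. Detection calls were not used here. The table held 18952 probe sets, of which 183 platform controls were left out of the tests and 18769 were tested. The platform annotation gave 1 gene for 13647 of them, several for 402 and none for 4720, which are unnamed here, not without a gene. Symbols were updated through the gene identifier for 13544 of the 13647, and 103 kept the annotation's symbol. Gene names, synonyms and the order of neighbouring genes came from RefSeq's gene table of the Release 6 assembly, and start and end in that table served only to order genes and to find overlapping neighbours. Probe sets whose names carry s or x may share transcripts between genes.

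Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The prior SD was 0.0754 with 5.50 prior and 4 residual degrees of freedom. All adjusted p-values of genes and tested probe sets come from this limma fit. Those of platform control probe sets come from a limma fit that held the controls too. "Rose" and "fell" are used for what passed, and log2 changes are induced minus S2 control. A gene was represented by its probe set with the highest mean over all arrays among those naming it alone, which gave 11982 genes. Of the 1094 genes with several such probe sets, 16 had probe sets that passed in opposite directions. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, which is why no single value was tested that way.

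The design, the alternatives, the rule for named genes and 40 gene lists were fixed before the data were examined. Of 1457 list entries, 1383 were matched to a current gene and 1092 were measured. Lists with at least 5 measured genes, 38 in all, were tested with camera (preset correlation 0.01), adjusted over lists, with camera at an estimated correlation and fry as alternatives. A list "shifted" where it passed camera at the preset correlation, and its adjusted p is from that test unless another is named. Core histones (1 of 9 measured) and transposable elements (0 of 66 measured) were not tested. "Adjusted over the list alone" is the Benjamini-Hochberg adjustment within 1 list. The rule named BigH1, and the 8 largest rises and falls among genes that passed, whose arrays did not overlap between groups, whose higher mean was above the median of all probe sets and whose symbol was not a CG or CR number alone. It also named up to 2 passing members per direction, by smallest adjusted p, of lists that passed or had at least 3 passing members, and any member of the metallothionein and linker histone lists. Genes were parted into 5 equal groups by mean signal, and rises and falls were compared between the highest and lowest with Fisher's exact test.

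The alternatives were a filter on dim probe sets (mean above the median), centring on array medians or on ribosomal protein genes, a further quantile normalisation, trended robust moderation, array weights, the replicate number as a block, each array left out in turn, the mean of a gene's probe sets, 10 signal groups, and stricter thresholds (at least 2-fold, adjusted p under 0.01). The linker histone list without BigH1 was added after the data were seen. The fit was tested on simulated arrays with the real means and spread. For this comparison and 18769 probe sets it recovered 31 of 67 probe sets changed by a log2 of 0.25 (46.3%), 67 of 67 at 0.5 and 66 of 66 at 1, with 5 false calls among 181 (2.76%). A simulated list shifted by 0.25 passed, and 0 of 20 unshifted lists did. The simulated genes varied independently, whereas estimated correlations within the real lists reached 0.45. The simulation therefore does not show how often lists of correlated genes pass falsely. Far fewer probe sets were changed in it than the 27.3% that passed in the real data. Its Benjamini-Hochberg cut was therefore stricter, and the recovery at 0.25 does not carry over to the real fit. The control transcripts' 5′ minus 3′ differences were taken from the platform's control probe sets as a sign of RNA quality, with SEs from the 3 arrays per group.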

Results

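Gene expression was measured in Drosophila S2 cells, a line derived from late embryos that resembles macrophage-like blood cells. The series asks what the embryonic linker histone dBigH1, which occupies chromatin in the early embryo and the germline, does to active chromatin when it is made in these cells. A group of 3 arrays came from S2 cells described as wild type, called S2 control here. Another group of 3 arrays came from S2 cells with induced dBigH1. All cells received 1 mM copper sulphate for 24 h, which induces metallothionein promoters, and 25 ng of total RNA per sample was amplified and hybridised to Affymetrix Drosophila arrays. The median log2 signal of the 18952 probe sets lay between 6.31 and 6.33 on all 6 arrays. Across probe sets, which are not independent replicates, Pearson's r was 0.998 to 0.999 within groups and 0.993 between groups. The number of arrays limits the precision of every value.

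The first question was how strongly BigH1 itself was induced, and whether genes that respond to copper stood alike in both groups. All cells received copper, so the response to it could not be measured, only the levels under it. BigH1 rose from a log2 signal of 5.19 ± 0.295 (SD, n = 3) in S2 control to 13.46 ± 0.0218 (n = 3) in induced cells, a 307.9-fold change of the signal (log2 8.27, SE 0.12, adjusted p = 7.338e-10). The S2 control arrays read 4.86, 5.42 and 5.30 and the induced arrays 13.47, 13.47 and 13.43. Its level stood at the 30.7 percentile of all probe sets in S2 control and at the 99.5 percentile in induced cells. With a dim signal on one side and a signal near the top of the range on the other, both of which compress differences, this fold is closer to a lower bound than to an exact change of the RNA. Among the metallothioneins, copper-binding proteins whose genes respond to copper, MtnB fell by 1.65 on the log2 scale (SE 0.07, adjusted p = 3.048e-07), from 13.01 ± 0.0457 to 11.36 ± 0.140 (n = 3 each). MtnA stood at 13.95 and 13.99 (log2 change 0.04, adjusted p = 0.677). The log2 change was -0.06 for MtnC (adjusted p = 0.449) and -0.14 for MtnD (adjusted p = 0.0546), which did not pass. Of the copper transporters, Ctr1B rose by 0.27 from a low signal of 4.23, while Ctr1A fell by 0.26, the copper chaperone Atox1 fell by 0.25 and the metal transporter Mvl fell by 0.21. In the whole list of metallothioneins and copper handling, 2 of 17 measured members rose, 5 fell and 10 did not pass (2 and 6 adjusted over the list alone), and the list did not shift (adjusted p = 0.331). The cells with dBigH1 carry a transgene and were kept under hygromycin, whereas the S2 control was wild type, so a difference between the lines other than dBigH1 would appear in every comparison given here.

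**Figure D1:**
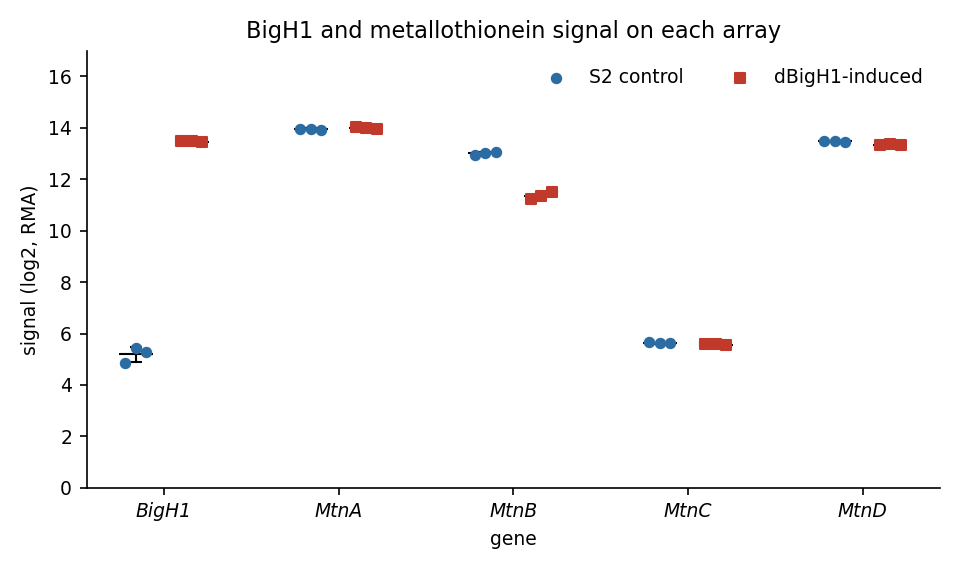
Log2 RMA signal (vertical axis) of BigH1 and the metallothionein genes (horizontal axis) on each array. Points are arrays (3 S2 control, 3 dBigH1-induced), and horizontal marks with bars are the mean and SD; BigH1 moved from 5.19 to 13.46 and MtnB from 13.01 to 11.36.

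The next comparison asked which other transcripts differed between induced and S2 control cells. Argk1, which encodes arginine kinase, fell most among the genes with a name of their own, from a log2 signal of 11.43 ± 0.0571 to 7.95 ± 0.0795 (n = 3 each), 11.1-fold (SE 0.06, adjusted p = 1.701e-09). The muscle genes TpnC4 (a troponin C) and Zasp52 (a Z-disc protein) fell by 2.94 (SE 0.08) and fell by 2.27 (SE 0.06) on the log2 scale. The co-chaperone gene stv fell by 2.50 (SE 0.06), firl fell by 2.45 (SE 0.06), the Rab11-binding protein gene nuf fell by 2.27 (SE 0.09), the extended synaptotagmin gene Esyt2 fell by 2.24 (SE 0.06) and the netrin gene NetB fell by 2.06 (SE 0.08). Apart from BigH1, Boot rose most, from 6.43 ± 0.187 to 8.86 ± 0.0742 (n = 3 each), 5.39-fold (SE 0.09, adjusted p = 9.313e-08). The lysosomal alpha-mannosidase genes LManI and LManII rose by 2.24 (SE 0.08) and 1.89 (SE 0.06). The adhesion protein gene Fas1 rose by 2.16 (SE 0.06), naz by 2.00 (SE 0.06), the sarcoglycan gene Scgalpha by 1.86 (SE 0.10) and l(3)neo38 by 1.55 (SE 0.06). Marf1 rose by 1.40 (SE 0.08), while its other probe set showed 0.22. The adjusted p of these 16 genes ran up to 2.057e-06, and they were ranked after passing over 5 higher and 4 lower genes known here by a CG or CR number alone.

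**Figure D2:**
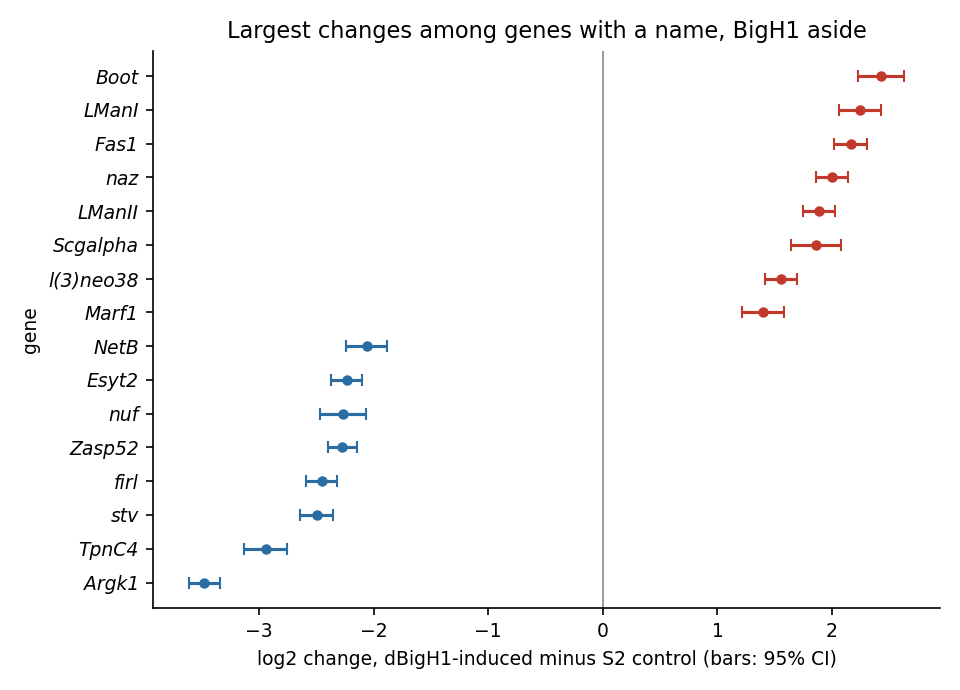
Log2 change, induced minus S2 control (horizontal axis), of the 8 largest rises and 8 largest falls among genes with a name (vertical axis), BigH1 left out. Points are estimates from 3 arrays per group and bars are 95% confidence intervals; the values run from -3.48 for Argk1 to 2.43 for Boot.

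In all, 2643 probe sets rose and 2480 fell of 18769 tested, 27.3%. The arrays of the groups did not overlap for 41.3% of probe sets, where chance alone gives 10%. Counted by gene, 1739 rose and 1918 fell of 11982, or 30.5%, and the groups did not overlap for 45.4% of genes against the same 10%. Most changes were small. The median size among the changed genes was 0.32 on the log2 scale, 43 genes rose and 133 fell by at least 2-fold, and an adjusted p under 0.01 left 1077 higher and 1279 lower genes. Among probe sets that are unnamed here, not without a gene, the largest rises were 4.45 (SE 0.12) and 4.21 (SE 0.09), and the largest falls were -2.83 (SE 0.09) and -2.34 (SE 0.06). Because the values were normalised between arrays from equal amounts of RNA, a change shared by all transcripts could not be seen.

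Lists of genes for pathways and cell types were compared next, to ask which groups of genes moved together. The lists of mitosis, DNA replication, ribosome biogenesis, spliceosome and oxidative phosphorylation genes shifted upwards in induced cells. Of 39 measured mitosis genes, 28 rose, 2 fell and 9 did not pass (30 and 2 adjusted over the list alone; median 0.28, adjusted p = 1.106e-07, and adjusted p = 0.242 with an estimated correlation). The kinesin gene Klp67A rose by 0.84 (SE 0.06) and the kinetochore gene Spc25 by 0.65 (SE 0.06), while the spindle pole gene tacc fell by 0.24 (SE 0.05). Of 38 DNA replication genes, 23 rose, 1 fell and 14 did not pass (27 and 1 adjusted over the list alone; median 0.26, adjusted p = 2.061e-07, and adjusted p = 0.420 with an estimated correlation). The helicase subunit Mcm6 rose by 0.54 (SE 0.05) and the primase subunit Prim1 by 0.46 (SE 0.05), and the member that fell was the origin recognition subunit Orc4, which fell by 0.35 (SE 0.08). Of 37 ribosome biogenesis genes, 21 rose and 16 did not pass (23 adjusted over the list alone; median 0.21, adjusted p = 7.802e-07, and adjusted p = 0.373 with an estimated correlation), among them the snoRNP gene NHP2, which rose by 0.47 (SE 0.05), and l(1)G0020 by 0.43 (SE 0.05).

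Of 32 spliceosome genes, 17 rose, 1 fell and 14 did not pass (19 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.000205, and adjusted p = 0.420 with an estimated correlation). The core snRNP genes SmD3 and SNRPG rose by 0.51 (SE 0.07) and 0.36 (SE 0.05). Of 39 genes of oxidative phosphorylation, 4 rose and 35 did not pass (2 adjusted over the list alone). The list passed (median 0.07, adjusted p = 0.0141), but with an adjusted p = 0.677 with an estimated correlation, 0.0936 in fry, 0.0663 without S2 control replicate 2 and 0.0599 without dim probe sets (0.00500 to 0.677 over all camera settings). Its members ND-18, a complex I subunit, and ATPsynE, an ATP synthase subunit, rose by 0.61 (SE 0.07) and 0.23 (SE 0.05). The neighbouring groups of the protein synthesis machinery did not shift. Of 27 translation factor genes 1 rose and 26 did not pass (1 adjusted over the list alone; adjusted p = 0.362). Of 18 aminoacyl-tRNA synthetase genes 3 rose, 3 fell and 12 did not pass (3 and 4 adjusted over the list alone; adjusted p = 0.878), with alpha-PheRS up by 0.38 and CysRS, which fell by 0.30. Of 31 measured cytosolic ribosomal protein genes, 0 passed in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The list's median was 0.01, its adjusted p = 0.694 in camera and 0.390 in fry. These were 31 of 82 listed genes, and their mean log2 signal was 13.39 in S2 control, so near the top of the range that a change may be hidden.

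Chromatin genes, the class nearest to the induced histone, were taken separately. Of 55 genes for histone modification and remodelling, 20 rose, 4 fell and 31 did not pass (22 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.00179, and adjusted p = 0.242 with an estimated correlation). The Polycomb group gene Sfmbt rose by 0.85 (SE 0.08) and the remodelling ATPase gene brm by 0.30 (SE 0.05), while the remodeller gene Chd3 fell by 0.97 (SE 0.08) and the deacetylase gene HDAC6 fell by 0.56 (SE 0.06). Of 27 linker histone and architectural protein genes, 11 rose, BigH1 included, 2 fell and 14 did not pass (12 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.0211, and adjusted p = 0.242 with an estimated correlation). Without BigH1, a setting chosen after the data were seen, the list did not pass (median 0.06, adjusted p = 0.0699), nor without dim probe sets (adjusted p = 0.0699; 0.00647 to 0.242 over all camera settings). The chromodomain gene Chro rose by 0.43 (SE 0.06), the H3 kinase gene JIL-1 by 0.39 (SE 0.05), pzg by 0.38 (SE 0.08), HP1c by 0.34 (SE 0.07), pita by 0.25 (SE 0.05) and the histone chaperone gene Nph by 0.22 (SE 0.05), while the topoisomerase gene Top1 fell by 0.46 (SE 0.06). The insulator genes CTCF, BEAF-32 and su(Hw) did not pass, with log2 changes of -0.09, 0.02 and 0.05, although a dimmer probe set of CTCF rose by 0.81 (SE 0.08, adjusted p = 5.143e-05). Of other insulator genes, mod(mdg4) rose by 0.17 (SE 0.05, adjusted p = 0.0383), with -0.02 to 0.54 on its other probe sets. Ibf2 stood at -0.23 to -0.16 with 1 array left out in turn. Of 53 genes of the RNA polymerase II machinery, 11 rose, 1 fell and 41 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.0595); the Mediator gene MED1 rose by 0.32 and MED14 fell by 0.29.

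The lists that shifted downwards in induced cells were those of oxidative stress, heat shock, proteasome, lysosome, Imd, lamellocyte and JNK genes, while other stress and immune lists (Toll, JAK/STAT, unfolded protein response and DNA damage) did not shift. Of 32 genes of oxidative stress and glutathione, 20 fell and 12 did not pass (3 higher and 21 lower adjusted over the list alone; median -0.24, adjusted p = 3.481e-06, and adjusted p = 0.194 with an estimated correlation). The glutathione synthesis gene Gclm fell by 0.88 (SE 0.08) and the cytochrome P450 gene Cyp6a8 fell by 0.85 (SE 0.06). Of 17 heat shock protein genes 9 fell and 8 did not pass (9 adjusted over the list alone; median -0.18, adjusted p = 0.000291, and adjusted p = 0.420 with an estimated correlation), with Hsp26 lower (fell by 0.57, SE 0.07) besides stv. Of 27 proteasome genes 8 fell and 19 did not pass (9 adjusted over the list alone; median -0.10, adjusted p = 0.00316, and adjusted p = 0.497 with an estimated correlation); Rpn8 fell by 0.40 (SE 0.05) and Prosbeta7 fell by 0.25 (SE 0.05). Of 37 lysosome and autophagy genes, 9 fell, 1 rose and 27 did not pass (1 higher and 10 lower adjusted over the list alone; median -0.07, adjusted p = 0.0361, and adjusted p = 0.242 with an estimated correlation). The autophagy receptor gene ref(2)P fell by 0.56 (SE 0.05) and the cholesterol transporter gene Npc1a fell by 0.51 (SE 0.06), while LManII was the member that rose. The lysosome list did not pass in camera without S2 control replicate 1 (adjusted p = 0.0583), without induced replicate 1 (0.0559) or without induced replicate 2 (0.0605). Nor did it with the replicate number as a block (0.0539), and its adjusted p was 0.0289 to 0.242 over all camera settings.

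Among the immune lists that shifted, the antimicrobial peptide and Imd pathway list had 20 measured genes, of which 10 fell, 2 rose and 8 did not pass (3 higher and 11 lower adjusted over the list alone; median -0.18, adjusted p = 0.00126, and adjusted p = 0.242 with an estimated correlation). The antifungal peptide gene Drs, known chiefly as a Toll target, fell by 1.73 (SE 0.09) and the recognition protein gene PGRP-LA fell by 1.61 (SE 0.06). The members that rose were PGRP-LB, an amidase known to restrain the pathway, by 0.27 (SE 0.06) and the caspase gene Dredd by 0.24 (SE 0.06). Lamellocytes are the blood cells that encapsulate parasites, and of their 15 measured marker genes 9 fell and 6 did not pass (9 adjusted over the list alone; median -0.23, adjusted p = 0.000317, and adjusted p = 0.242 with an estimated correlation). The integrin gene ItgaPS4 fell by 1.75 (SE 0.12) and the prophenoloxidase gene PPO3 fell by 1.19 (SE 0.06). Of 15 JNK pathway target genes 9 fell, 1 rose and 5 did not pass (1 higher and 9 lower adjusted over the list alone; median -0.17, adjusted p = 0.0105, and adjusted p = 0.242 with an estimated correlation). The transcription factor gene Ets21C fell by 0.95 (SE 0.06) and the relaxin-like hormone gene Ilp8 fell by 0.61 (SE 0.06), while the TNF receptor gene wgn rose by 0.74 (SE 0.05). The lamellocyte and JNK lists share 4 measured genes.

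**Figure D3:**
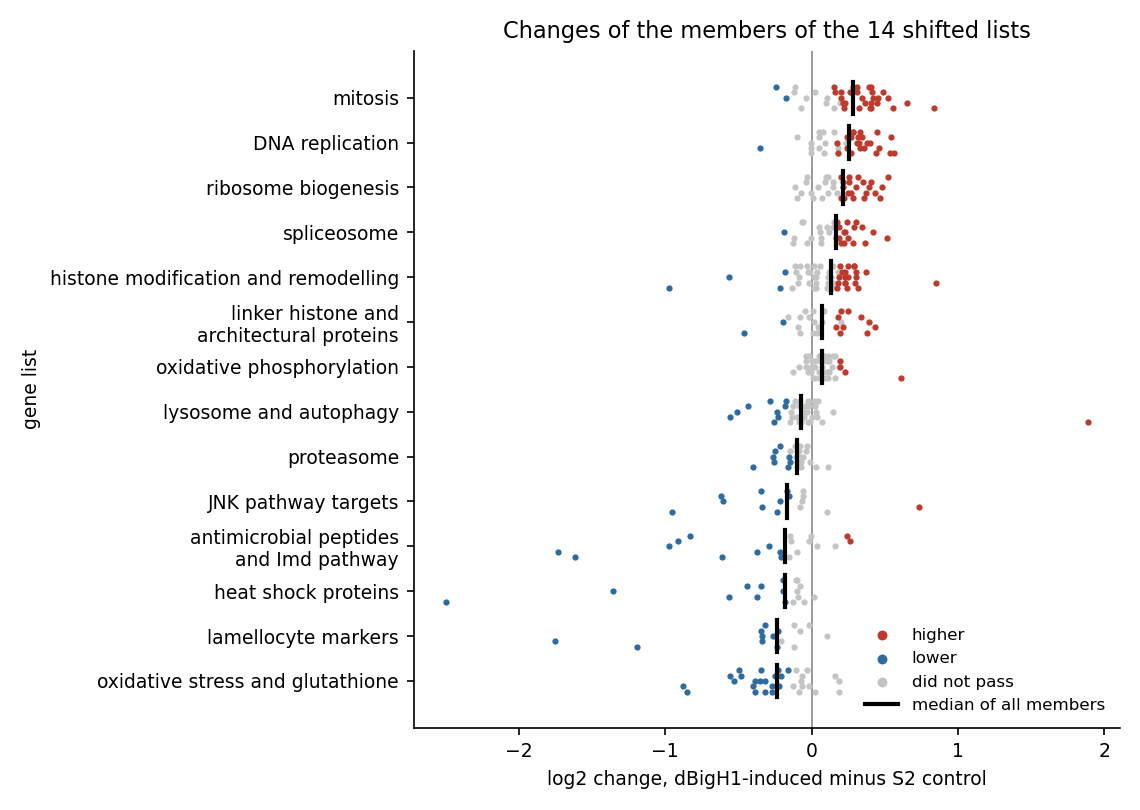
Log2 change, induced minus S2 control (horizontal axis), of each measured member of the 14 lists that passed (vertical axis), estimated from 3 arrays per group. Points are genes, coloured as higher, lower or not passing, black bars are medians over all members, and BigH1 (8.27) is not drawn; medians run from -0.24 for oxidative stress and glutathione to 0.28 for mitosis.

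Of the 38 lists tested, 7 shifted upwards and 7 downwards with the preset correlation, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.194 and 7 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's own genes move one way on balance and compares them with no other genes, passed 23 lists. Some of these did not shift in camera: SREBP targets (adjusted p = 0.00139 in fry), JAK/STAT (0.00151), Hox and Polycomb targets (0.00154) and unfolded protein response (0.00162). The same held for muscle (0.00203) and metallothioneins (0.00325). The ecdysone, RNA polymerase II, crystal cell and plasmatocyte lists passed fry at 0.0186 to 0.0404. Signs of RNA quality also differed between the groups beside both the higher and the lower lists. The 5′ minus 3′ signal of the control probe sets for Act5C was -1.26 ± 0.0869 in S2 control and -1.79 ± 0.0778 in induced cells (n = 3 each, difference -0.53, SE 0.07). That of the second GAPDH series was -1.92 ± 0.0443 and -1.73 ± 0.0487 (difference 0.19, SE 0.04). The differences for GAPDH, actin, eIF-4a and 18S rRNA were -0.08, 0.03, -0.08 and -0.04.

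The identity of the cells was followed with blood cell and other immune lists. Of 34 plasmatocyte and S2 marker genes, 12 rose, 8 fell and 14 did not pass (13 and 11 adjusted over the list alone; adjusted p = 0.531). The peroxidasin gene Pxn rose by 0.65 and the globin gene glob1 by 0.55, while the scavenger receptor gene Sr-CI fell by 1.09 and the haemocyte gene He fell by 0.71. Of 10 crystal cell marker genes, 1 rose, 3 fell and 6 did not pass (2 and 3 adjusted over the list alone; adjusted p = 0.422), among them Naam, which fell by 0.59. Of 16 fat body genes, 2 rose, 1 fell and 13 did not pass (2 and 1 adjusted over the list alone; adjusted p = 0.952); Apoltp rose by 0.75 and the lipid droplet gene Lsd-1 fell by 0.73. Of 18 Toll pathway genes, 2 rose, 4 fell and 12 did not pass (2 and 4 adjusted over the list alone; adjusted p = 0.694). The recognition gene GNBP3 rose by 0.62 and the ligand gene spz by 0.43, whereas the protease gene grass fell by 0.60 and the transcription factor gene Dif fell by 0.41. Of 13 JAK/STAT and Turandot genes, 3 fell and 10 did not pass (3 adjusted over the list alone; adjusted p = 0.362), with the ligand gene upd2 lower (fell by 1.53, SE 0.08).

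Developmental and tissue-restricted genes moved both ways without a shift of any of their lists in camera, although fry passed the Hox and muscle lists. Several of these lists were dim, so changes may be hidden. Their mean log2 signal in S2 control was 5.13 (Hox), 5.15 (testis) and 5.91 (muscle), with a median of 6.33 over all probe sets. Of 61 Hox and Polycomb target genes, 7 rose, 7 fell and 47 did not pass (7 and 7 adjusted over the list alone; adjusted p = 0.362). The homeotic regulator gene tsh fell by 1.19 and prd fell by 1.44 to a low signal of 3.61, while pnr rose by 0.35. Of 47 germline and piRNA pathway genes, 10 rose, 8 fell and 29 did not pass (11 and 9 adjusted over the list alone; adjusted p = 0.475). The germ cell differentiation genes bgcn and bam rose by 0.95 and 0.62, whereas mael fell by 0.90. Of 42 testis-specific genes, 3 rose, 3 fell and 36 did not pass (3 and 3 adjusted over the list alone; adjusted p = 0.728), including topi, which fell by 0.78. Of 21 muscle genes, 1 rose, 5 fell and 15 did not pass (1 and 6 adjusted over the list alone; adjusted p = 0.109). Besides Zasp52, the myogenic regulator gene nau fell by 1.42, and TpnC73F rose by 1.28 on 1 probe set with -0.12 on its other. Of 31 neuronal genes, 3 rose, 3 fell and 25 did not pass (3 and 3 adjusted over the list alone; adjusted p = 0.878), with Rbp9 up by 0.91 and Nrx-1, which fell by 0.71.

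Signalling, hormone and adhesion lists were mixed as well. Of 32 epithelial and imaginal disc genes, 4 rose, 5 fell and 23 did not pass (4 and 5 adjusted over the list alone; adjusted p = 0.847); the coactivator gene yki fell by 0.39. Of 14 Notch target genes, 3 rose, 3 fell and 8 did not pass (3 and 4 adjusted over the list alone; adjusted p = 0.878), with E(spl)mdelta-HLH up by 0.65 and E(spl)mbeta-HLH, which fell by 0.59. Of 19 genes in the list of Hippo, Wnt and EGFR pathway targets, 3 rose, 4 fell and 12 did not pass (3 and 4 adjusted over the list alone, and adjusted p = 0.952 for the list in camera). Its member kek1 rose by 0.45, and Dad, held by the list though known chiefly as a Dpp target, fell by 0.70. Of 31 ecdysone response genes, 3 rose, 4 fell and 24 did not pass (3 and 4 adjusted over the list alone; adjusted p = 0.791); the nuclear receptor genes Eip78C and EcR fell by 0.83 and fell by 0.77. Of 33 cytoskeleton and cell adhesion genes, 9 rose, 13 fell and 11 did not pass (9 and 14 adjusted over the list alone; adjusted p = 0.475), with Fas1 the largest rise and the tubulin gene betaTub60D, which fell by 0.54. The median and mean differed in sign for the cytoskeleton (-0.09 and 0.0023), epithelial (0.0024 and -0.02), DNA damage (0.04 and -0.01), fat body (-0.05 and 7e-04) and Hippo, Wnt and EGFR lists (0.04 and -0.04). The test pointed down for the cytoskeleton and epithelial lists and up for the other 3.

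Metabolic and damage lists made up the rest. Of 17 genes of cholesterol and fatty acid synthesis (SREBP targets), 6 fell and 11 did not pass (6 adjusted over the list alone; adjusted p = 0.0595), with the phospholipid synthesis gene Pcyt1 lower (fell by 0.54) and the acetyl-CoA synthase gene AcCoAS lower (fell by 0.38). Of 28 genes of the unfolded protein response and ATF4, 7 rose, 4 fell and 17 did not pass (7 and 4 adjusted over the list alone; adjusted p = 0.365). The serine synthesis genes CG6287 and CG11899 rose by 1.65 (SE 0.06) and 0.66 (SE 0.05), while the asparagine synthetase gene AsnS fell by 0.75 (SE 0.06) and aay, the phosphatase of serine synthesis, fell by 0.40 (SE 0.07). Of 14 glycolysis genes, 2 rose, 1 fell and 11 did not pass (2 and 1 adjusted over the list alone; adjusted p = 0.406); Gpdh1 fell by 0.36. Of 31 genes of the DNA damage response, p53 targets and apoptosis, 9 rose, 7 fell and 15 did not pass (9 and 9 adjusted over the list alone; adjusted p = 0.694). The repair genes nbs and Ku80 rose by 0.44 and 0.30, and the caspase gene Dronc fell by 0.40.

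The last comparison asked whether the direction of change depended on how strongly a gene is expressed, since the series is about active chromatin. Genes were ordered by their mean signal over all 6 arrays and parted into 5 equal groups. In the lowest group 41 genes rose and 115 fell (6.51% changed), in the next 200 and 289 (20.4%), in the middle group 482 and 500 (40.97%), in the next 568 and 517 (45.3%) and in the highest 448 and 497 (39.4%). The odds of a rise against a fall were 2.53 times higher in the highest than in the lowest group (95% CI 1.71 to 3.79, Fisher's exact test across genes, two-sided, p = 5.939e-07). The median log2 change was between -0.02 and 0.03 in every group. Without dim probe sets, which takes away the genes of the 2 lowest groups before the rest are parted again, the log2 odds ratio went from 1.34 to 0.16 (Fisher's exact test, p = 0.341; 1.706e-08 to 0.341 over all settings). Genes are not independent of each other, so these p-values describe the lists of genes and not the cells.

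**Figure D4:**
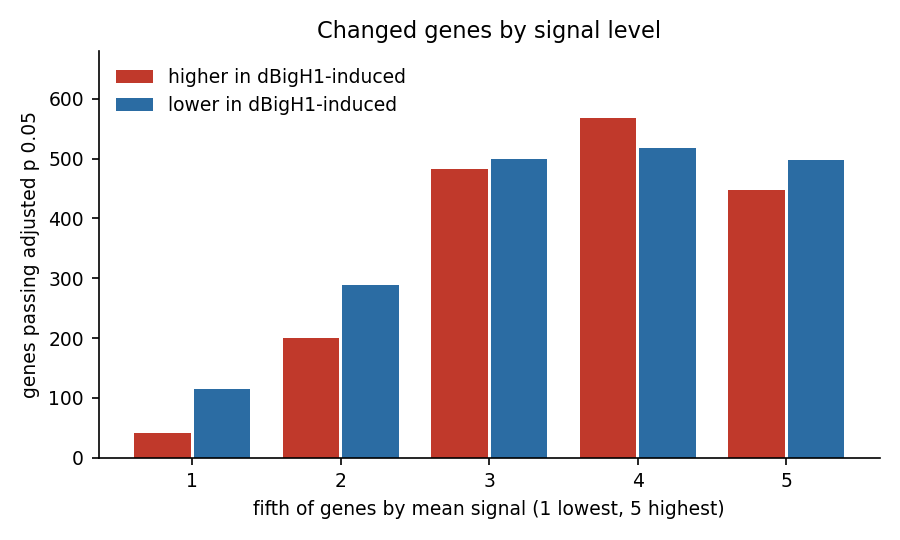
Number of genes that passed an adjusted p of 0.05 (vertical axis) in 5 equal groups of genes by mean log2 signal over 6 arrays (horizontal axis, 1 lowest to 5 highest). Red bars are genes higher and blue bars genes lower in induced cells; 41 rose and 115 fell in the lowest group, 448 and 497 in the highest.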

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

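The tests of RNA integrity, of the copper response and of the transfected line, and which lists made up the higher and lower groups, were chosen after the result was seen.

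A platform control probe set outside the tests rose by 5.55 on the log2 scale, from 4.68 ± 0.155 in S2 control to 10.23 ± 0.0478 in induced cells (n = 3 each, adjusted p = 3.486e-10), a signal in data that no comparison used. It was the 1 control probe set of 183 that rose, while 9 fell, in the fit that held the controls. What it detects was not established here.

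The 3 against 3 arrays make 10 splits, too few for a share under 0.05. Each of the other splits mixes arrays of both groups, so the difference between the groups enters their spread. Their values therefore do not show what chance alone gives. The real split gave 2643 probe sets higher and 2480 lower, and 1739 genes higher and 1918 lower, each reached by 1 of the 10 splits, the real one, with 0 as the highest of the others. For gene lists the real split gave 14 shifted lists, also reached by 1 split, and the highest of the others gave 9.

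The 7 lists that passed lower span oxidative stress, heat shock, proteasome, lysosome, lamellocyte, Imd and JNK genes. A bias of the normalisation that depends on signal was set against random lists matched on mean signal. The median of 7 of 7 lists lay outside the central 95% of 10000 such lists. These lists had been chosen because they passed, and random lists ignore correlation between genes, so that share is no separate support. The median log2 change of the 5 signal groups was only -0.0228 to 0.0304. RMA itself holds such medians near 0, so they cannot decide whether it left a bias by signal. A weaker copper response could lower stress genes, but MtnA, MtnC and MtnD had a median change of -0.0567 (MtnB fell by 1.65), and MtnA and MtnD lay so near the top of the signal range that a change may be hidden. Every array came from cells with copper, so the response itself was not measured. A difference of the transfected line other than dBigH1 cannot be told apart from dBigH1, because 0 arrays came from that line without induction. An effect of dBigH1 on these genes stays open as a hypothesis, beside the RNA quality differences given for both groups of lists.

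Of the lists that passed higher, 5 were weighed together (mitosis, DNA replication, ribosome biogenesis, spliceosome and oxidative phosphorylation). The lists of translation factors, aminoacyl-tRNA synthetases and cytosolic ribosomal proteins did not shift (adjusted p = 0.362, 0.878 and 0.694 in camera). Ribosomal protein signals lay so near the top of the range that a change may be hidden. With an estimated correlation, 0 lists passed. Signal-dependent bias was tested in the same way, and 5 of 5 lists lay outside the central 95% of matched random lists, with the same limits. The medians of the signal groups given above cannot decide this here either. Of the lists that passed higher but were not weighed, histone modification lay outside its matched range. The linker histone list without BigH1 lay inside (median 0.0594, range -0.0767 to 0.0987). Poorer RNA in the induced samples would lower the 5′ minus 3′ signal in all 6 series of control probe sets; the median change was -0.0591, with 4 series lower and 2 higher. Act5C stood at -0.53 (SE 0.07), but the series named actin stood at 0.03 (SE 0.02). The GAPDH series also disagreed with each other (-0.08, SE 0.03, and 0.19, SE 0.04), so RNA quality stays open. The line stays open too, with 0 arrays of uninduced transfected cells, and a difference of that line and an effect of dBigH1 cannot be told apart.

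Changed genes might cluster where the lines differ in copy number over long stretches. Along the gene order, 8.46% of the 2932 changed genes above the median signal lay in windows of 41 neighbours whose median was beyond the limit of 1000 shuffled orders (0.18). Of all 6922 such genes, 6.47% lay there. This argues against copy-number differences that move the median of such a window beyond that limit as the cause of most changes. Smaller shifts over long stretches would stay within the limit and were not covered. Stretches much shorter than a window move its median little and were not covered either. The 8 stretches themselves stay open, such as 93 genes from CG5543 to CG4622, of which 49 fell and 5 rose (lowest window median -0.38), and 56 from Trf4-1 to c12.1, of which 26 rose and 3 fell. DNA was not measured here, and no biological explanation of the stretches was tested.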

How the results depend on the processing

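The linker histone list without BigH1 was chosen after the result was seen. The BigH1 change and the log2 odds ratio of direction by signal kept their sign in all settings tried, and 0 probe sets passed in opposite directions between any setting and the fit reported. Demanding at least 2-fold left 98 probe sets higher and 161 lower and 43 genes higher and 133 lower; an adjusted p under 0.01 left 1656 and 1613 probe sets and 1077 higher and 1279 lower genes, by construction. Camera with estimated correlations left 0 lists: it tests on 4 residual degrees of freedom, and 8 of the 14 lists also had a correlation above the preset 0.01 (6 did not). Fry, which tests something else, gave 23 lists. The dim filter brought the log2 odds ratio of direction by signal to 0.16 (Fisher's exact test, p = 0.341), with the dim genes taken away. Other settings kept counts within 1.5 times, and 50.01 to 53.6% of passing probe sets were higher. Without 1 array, probe sets numbered 2030 to 2387 higher and 1941 to 2329 lower, genes 1285 to 1554 and 1526 to 1805, lists 13 to 16, the BigH1 change 8.10 to 8.38 and the log2 odds ratio 0.81 to 1.34. With the replicate number as a block, 2399 probe sets were higher and 2242 lower, 1549 genes higher and 1727 lower, 13 lists passed (the lysosome list had adjusted p = 0.0539), BigH1 changed by 8.27 and the log2 odds ratio was 1.20. The values gave no sign that the numbers pair the samples: same-numbered deviations correlated at 0.04, -0.10 and 0.01, and 2 of 6 arrays correlated best with their own number. With so few arrays, pairing cannot be excluded. For named genes, 1112 of 1130 values in other settings and 923 of 984 with 1 array left out kept direction and side of the threshold; for lists, 122 of 141 and 80 of 84. Signs turned only for 6 genes near 0 that passed in no setting: Lhr (-0.0183 with quantile normalisation, -0.0354 to 0.0535 with an array left out), Ibf1 (-0.0019 with array weights, -0.0282 to 0.0338), su(Hw) (-0.0335 to 0.1028), Ctr1C (-0.0631 to 0.0433), BEAF-32 (-0.01 to 0.046) and HP1e (-0.0679 to 0.017); the cause was not tested. Signal over background limits what can be seen: 6.51% of genes in the lowest signal group passed against 45.3% in the next to highest, and arrays have no detection call here.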

Other observations

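The splits of the families, the distance series, the pairs without overlapping genes, the genes named as neighbours and the family members named were chosen after the result was seen.

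Gene families outside the fixed lists were taken from symbols alone, after the main results but before their own test, and 4 of 32 passed. Whether families outside the lists shift as groups stays open: the 10 splits of the arrays are too few for a share under 0.05, and the highest of the other splits also passed 4 families. Those other splits mix both groups, so they do not show what chance alone gives. Of 20 nucleoporin genes, 10 rose and 10 did not pass (median 0.20, adjusted p = 0.000634, and adjusted p = 0.746 with an estimated correlation), with Nup205 and Nup35 up by 0.45 (SE 0.07) and 0.42 (SE 0.05). Of 69 mitochondrial ribosomal protein genes, 16 rose and 3 fell (median 0.10, adjusted p = 0.0161, and adjusted p = 0.971 with an estimated correlation), with mRpL30 up by 0.44 (SE 0.07). Of 8 RNA polymerase III subunit genes, 4 rose (median 0.18, adjusted p = 0.0309, and adjusted p = 0.816 with an estimated correlation), with Polr3A up by 0.28 (SE 0.06). Of 31 genes of tetraspanins, membrane proteins of the cell surface and endosomes, 13 fell and 3 rose (median -0.17, adjusted p = 0.00224, and adjusted p = 0.746 with an estimated correlation). Tsp42Ea fell by 0.88 (SE 0.06) and Tsp42Eo fell by 0.59 (SE 0.06), while Tsp29Fb rose by 0.98 (SE 0.10). The alpha-mannosidase family was added because LManI had risen. Members of the fixed lists were left out of families, and so LManII, which also rose, was not counted; of the other 5 members LManI rose, and the family did not pass (adjusted p = 0.851).

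Neighbouring genes may change together. Of 1408 pairs of adjacent genes that both passed, 990 (70.3%) moved in the same direction, against 47.3 to 53.04% in the central 95% of 1000 shuffled gene orders, and 0 of the 1000 reached as high. Without genes that overlap each other the share was 68.9% (762 of 1106). It was 60.8% at 2 genes apart, 55.5% at 5, 52.4% at 10 and 53.2% at 100. The lysosomal alpha-mannosidase genes LManI and LManII are adjacent and both rose, CG10089 next to stv fell by 1.41, and CG30440, at 2 genes from TpnC4, fell by 3.16. Other neighbours moved the opposite way: Ugt50B3, between CG30440 and TpnC4, rose by 0.69, and Tgi, at 2 genes from stv, rose by 0.38. For Argk1 and Fas1, none of the 2 neighbours on either side passed, so neither gene is part of such a pair. Whether shared regulation, short copy-number differences or transcripts read by neighbouring probe sets make the pairs alike was not tested.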
